A study of Mus musculus with 15 samples.

How the data were processed

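The series holds RNA sequencing (Illumina TruSeq RNA kit) of 15 samples of neonatal mouse heart cells in 5 groups of 3, taken from the sample titles and genotype labels. Expected counts per gene, estimated counts of reads that need not be whole, were deposited as 1 table for all samples. Per the submitters' processing notes, which list tools without their order or settings, fastp 0.21.0, FastQC, MultiQC, Bowtie2 2.3.5.1, RSEM 1.3.1 and DESeq2 were used. The genome build and annotation are not given in the sources used here. RSEM divides reads that match several genes between them, so counts of genes with close copies are uncertain, and so are genes that overlap on opposite strands, since strand handling is not stated. Expected counts were rounded to whole numbers before testing. The table held 53762 genes, and every column was mapped to a sample by its name.

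Replicates were compared before they were used. Over the 15 pairs within groups, the chi-square statistic per degree of freedom was 2.72 to 6.37, except for the pairs of KO_CT replicate 1 with replicates 2 and 3, at 13.5 and 19.4. KO_CT replicate 1 thus stood apart from its group. No pair differed by as little as sampling noise, and each library counted as 1 replicate. Total counts ranged from 16714900 to 34246400. The common biological coefficient of variation was 0.0637, which sets the precision of most differences.

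Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures drawn in Python 3.11.15 with matplotlib 3.10.9. All 15 libraries entered 1 fit with a mean per group, so that the groups shared an estimate of the spread. Genes were kept by filterByExpr (17250 genes), scaled by TMM, and tested with edgeR's robust quasi-likelihood test, and a gene is called when its Benjamini-Hochberg adjusted p is below 0.05. The 6 comparisons between groups and the interaction of label and treatment were adjusted separately. CPM values are edgeR's counts per library size after TMM scaling, given as mean ± SD over 3 libraries, and log2 fold changes are given ± SE. Gene lists were tested with limma camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with an estimated one, and with fry, which tests a list against no change. Adjustment was over 37 lists per comparison. A further list, of erythroid markers, had 3 measured members and was not tested. The tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where a choice is said to follow it.

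Genes are named by rule. Atf3 and Fancd2 are always named. For each comparison the 6 largest rises and 6 largest falls qualify (4 and 4 for the interaction, 3 and 3 for KO_HA against WT_HR), among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, leaving out gene models, pseudogenes, unnamed and mitochondrial genes. Up to 4 called members with the smallest adjusted p are taken per described list, and 8 genes with the largest opposite changes for the virus comparison.

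Pseudogenes of any type were linked to parent genes in GENCODE M21 when at least 20% of their 31-base words occurred in the parent transcript. This gave 287 pseudogenes of 215 parents with a mean count of at least 5. Some links, such as Rps7-ps2 to Odc1, join genes of different names and may be wrong. The pseudogene share of a library is the median, over 17 ribosomal protein families, of the percent of family counts on pseudogenes. Among these families is that of Rpl10-ps3, a parent gene itself named as a pseudogene. It was measured after the data had been seen.

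The procedure was tested on simulated counts with known fold changes, drawn from the means, dispersions and library sizes of each comparison. In each simulation 67 genes were changed 1.25-fold, 67 genes 1.5-fold and 66 genes 2-fold, and the rest were left unchanged. At 2-fold, 75.8% of changed genes were recovered for KO_CT against WT_CT, 75.8% for WT_HR against WT_CT, 71.2% for KO_HR against KO_CT, 77.3% for KO_HR against WT_HR, 80.3% for KO_HA against KO_HR, 65.2% for KO_HA against WT_HR and 72.7% for the interaction. At 1.25-fold the figures were 34.3% for KO_HR against WT_HR and 13.4% for the interaction. Between 3 and 10 of about 17049 unchanged genes were called. The real comparisons between groups called 1538 to 11828 genes, many more than were changed in the simulations. The adjusted p depends on how many genes change, so these recoveries and false calls need not hold for those comparisons. With no list shifted, no list was called in the simulation of KO_HR against WT_HR by camera or fry. Genes were drawn independently there, so it does not test how correlation between genes affects the list tests.

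The alternatives were DESeq2's size factors in edgeR, total counts alone, no filter on low counts, a mean of at least 1 CPM, DESeq2's own test, the replicate number as a block, a fit of only the 6 libraries compared, and each library left out in turn. After seeing the data 3 were added: pseudogene reads added to their parent genes, the pseudogene share as a covariate, and only libraries with a share over 65%. Correlations between comparisons that share libraries were set against 20 simulations of unchanged groups. Coordinates are from GRCm38 and GENCODE M21, 1-based.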

Results

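RNA was sequenced from cultured heart cells of newborn C57BL/6 mice, a mixture of cardiomyocytes with fibroblasts, smooth muscle, endothelial and immune cells. The 15 libraries formed 5 groups of 3. Untreated cells labelled wild type (WT_CT) or Atf3 knockout (KO_CT) were set beside cells of both labels after hypoxia and reoxygenation (WT_HR and KO_HR), a culture model of ischaemia and reperfusion. In it the medium is replaced by saline without oxygen for 3 h, and medium and oxygen are then given back for a time that the labels do not state. In the last group (KO_HA), cells labelled knockout received an adenovirus carrying Atf3 before the same treatment. A control virus group named in the protocol was not analysed here, so an effect of the virus itself is not separated from one of the Atf3 it carries. Total counts were 16714900 to 21129000 per library, and 34246400 in KO_CT replicate 1. The first principal component held 68.2% of the variance and parted the 6 untreated libraries from the 9 treated ones. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Values in parentheses after a gene are log2 fold changes ± SE.

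The libraries also differed in how reads were divided between ribosomal protein genes and their pseudogenes. Over 17 ribosomal protein families, the median share of family counts on pseudogenes, called the pseudogene share below, was 66.1 to 71.3% in 9 libraries. It was 41.7 to 45.4% in the 3 KO_HR libraries, 59.6% and 57.1% in KO_CT replicates 2 and 3, and 61.1% in KO_HA replicate 3. The median over all 55 families measured, ribosomal or not, did not set KO_HR apart in this way. It was 34.9 to 38.1% in KO_HR, 36.9% and 36.8% in KO_CT replicates 2 and 3, and 37.9% in KO_HA replicate 3. The labels name no batch. All genes named as mitochondrially encoded, not mRNAs alone, held 4.21 to 4.76% of counts in KO_HR, 6.11 to 6.27% in WT_HR and 7.1 to 7.48% in KO_HA. Reads placed on nuclear copies are left out there. These copies held 66.8 to 88.6% of the mt-Co3 family counts in KO_HR and at most 19.3% in WT_HR, which enlarges the gap.

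**Figure D1:**
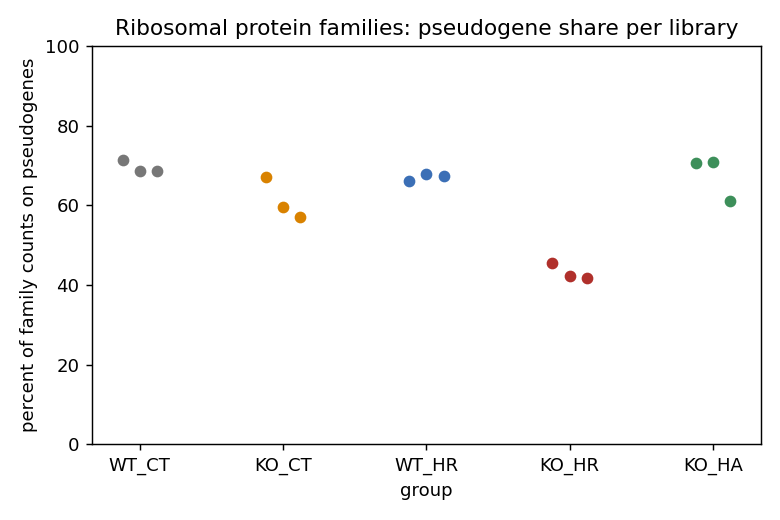
Pseudogene share of each library (percent of family counts on pseudogenes, median over 17 ribosomal protein families) by group, 1 point per library. The 3 KO_HR libraries lie at 41.7 to 45.4%, below all other libraries.

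Atf3 encodes a stress-induced transcription factor of the ATF/CREB family, and its transcript was not lost from the libraries labelled KO. It stood at 10.1 ± 0.454 CPM (SD, n = 3) in WT_CT and 6.32 ± 0.243 in KO_CT, and rose to 364 ± 7.33 CPM in WT_HR and 290 ± 14.5 in KO_HR. The KO_HR level was 79.6% of the WT_HR level (log2 fold change -0.33 ± 0.05, adjusted p = 8.2e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In KO_HA, with the Atf3 virus, it was 296 ± 14.0 CPM. The KO_HA to KO_HR ratio had a 95% confidence interval of 0.957 to 1.09 (adjusted p = 0.67 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Counts per gene cannot show whether part of the gene is deleted, nor tell viral from cellular Atf3. Since Atf3 goes against the label, the groups are treated throughout as libraries labelled KO, and each direction given for them rests on the label alone. Wording on the virus rests on the KO_HA label in the same way, as Atf3 was not detectably higher there than in KO_HR. Atf3 lies on chromosome 1 at 191170296 to 191218039, minus strand, in GRCm38 with GENCODE M21. The build behind the counts is not given in the sources used here, and 92.9% of the gene names in the count table were found in that annotation.

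Fancd2, a protein of the Fanconi anaemia pathway for repair of DNA crosslinks, is the other gene of the series title. The title also names ferroptosis, an iron-dependent cell death by lipid peroxidation. Fancd2 (chromosome 6, 113531682 to 113597017, plus strand, same annotation) was a low transcript, at 7.85 ± 1.45 CPM (SD, n = 3) in WT_CT and 9.26 ± 0.597 in KO_CT. It fell with hypoxia and reoxygenation to 5.09 ± 0.599 CPM in WT_HR (log2 fold change -0.62 ± 0.16, adjusted p = 9.9e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In KO_HR it fell to 4.87 ± 0.714 CPM (log2 fold change -0.94 ± 0.15, adjusted p = 2.7e-06 in the same edgeR test with Benjamini-Hochberg adjustment). The difference between KO_HR and WT_HR did not pass it (adjusted p = 0.85 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with a 95% confidence interval of the ratio of 0.751 to 1.2. In KO_HA it was 8.14 ± 1.6 CPM, above KO_HR (log2 fold change 0.75 ± 0.16, adjusted p = 3.3e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the pseudogene share as a covariate this last log2 fold change was -0.04 and no longer called.

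**Figure D2:**
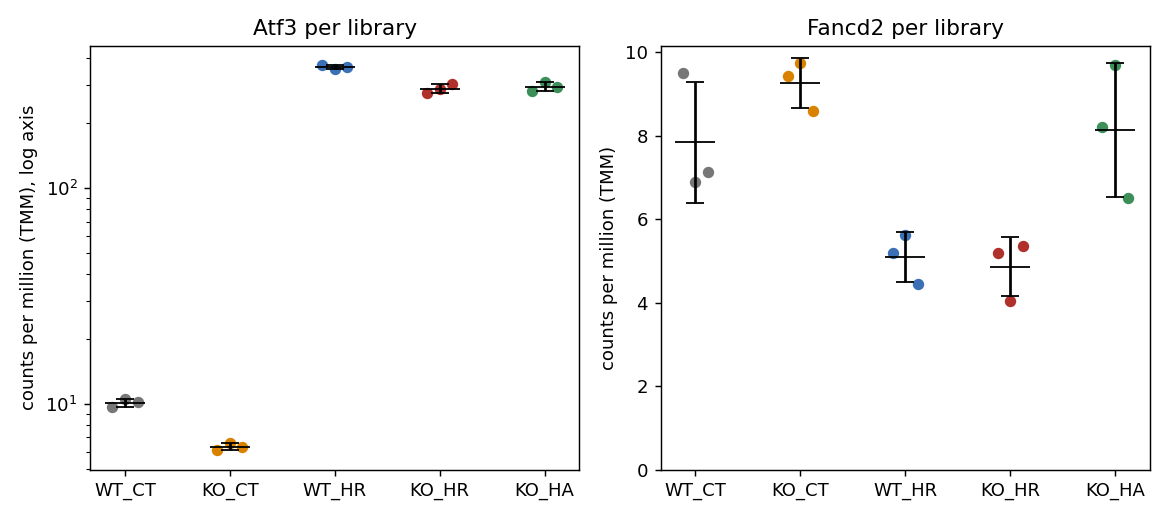
Atf3 (left, log axis) and Fancd2 (right) in CPM for each library by group, with the group mean (wide bar) and SD (whiskers). Atf3 lies near 10.1 CPM in WT_CT, 6.32 in KO_CT and between 290 and 364 in the treated groups, libraries labelled KO included.

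WT_HR against WT_CT asked what hypoxia and reoxygenation did to cells labelled wild type. Immediate early genes, the first to be transcribed after a stimulus, rose steeply. All 26 measured members rose, with a median log2 fold change of 2.50. Egr4 (7.96 ± 0.15), Fosb (6.97 ± 0.09) and Arc (6.16 ± 0.09) were among the 6 genes with the largest rise. Cardiomyocyte transcripts fell just as steeply: all 30 markers fell, with a median of -2.64 (camera adjusted p = 2.6e-19, adjusted p = 0.099 with an estimated correlation). Among them were Ckmt2 (-3.74 ± 0.07), the mitochondrial creatine kinase of muscle, and Csrp3 (-1.83 ± 0.06). The calcium release channel Ryr2 (-3.99 ± 0.16) and the adrenergic receptor Adrb1 (-3.96 ± 0.10) were among the largest falls. In all, 11791 of 17250 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5716 higher and 6075 lower, 1896 and 2080 of them by at least 2-fold.

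Several stress programmes rose in WT_HR. The p53 targets did (19 of 24 rose and 5 fell (19 and 5 adjusted over the list alone), camera adjusted p = 1.6e-06, adjusted p = 0.0047 with an estimated correlation), with Cdkn1a (2.11 ± 0.04), the cell cycle inhibitor p21, and Pmaip1 (2.69 ± 0.05). So did inflammatory cytokines and chemokines (24 of 30 rose and 1 fell (24 and 1 adjusted over the list alone), camera adjusted p = 1.7e-07, adjusted p = 0.026 with an estimated correlation), with Ptgs2 (3.42 ± 0.08) and Il1a (2.46 ± 0.09). NRF2 antioxidant genes (18 of 26 rose and 3 fell (18 and 3 adjusted over the list alone), camera adjusted p = 5.3e-06, adjusted p = 0.14 with an estimated correlation) rose by the preset test. So did genes that defend against ferroptosis (14 of 27 rose and 8 fell (14 and 8 adjusted over the list alone), camera adjusted p = 0.038, adjusted p = 0.22 with an estimated correlation). Among the leading genes, Slc7a11 (2.09 ± 0.07), the cystine importer, and Txnrd1 (1.90 ± 0.05) are on both lists. Hmox1 (3.14 ± 0.05) is on the NRF2 list and that of ferroptosis promoting genes, not on the defence list. Heat shock proteins moved likewise (12 of 20 rose and 5 fell (13 and 5 adjusted over the list alone), camera adjusted p = 0.0015, adjusted p = 0.15 with an estimated correlation), with Hspa1a (5.26 ± 0.07). ATF4 targets did too (16 of 30 rose and 10 fell (16 and 10 adjusted over the list alone), camera adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation), with Sesn2 (2.13 ± 0.05). Ferroptosis promoting genes went both ways (13 of 27 rose and 10 fell (13 and 10 adjusted over the list alone), camera adjusted p = 0.26, adjusted p = 0.50 with an estimated correlation). Among 28 Fanconi genes 15 fell and 1 rose (camera adjusted p = 0.073, adjusted p = 0.23 with an estimated correlation, 15 falling adjusted over the list alone).

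Energy metabolism fell. All 33 nuclear-encoded genes of oxidative phosphorylation fell (camera adjusted p = 9.7e-19, adjusted p = 0.083 with an estimated correlation), with Atp5a1 (-1.65 ± 0.04). So did most genes of fatty acid oxidation (21 of 24 fell and 1 rose (21 and 1 adjusted over the list alone), camera adjusted p = 1.7e-10, adjusted p = 0.057 with an estimated correlation), with Acadm (-2.27 ± 0.06). Glycolysis enzymes fell as well (13 of 15 fell and 2 rose (13 and 2 adjusted over the list alone), camera adjusted p = 1.7e-05, adjusted p = 0.22 with an estimated correlation), with Pfkm (-2.49 ± 0.06). Markers of several other cell types rose. Of the fibroblast markers 23 of 25 rose and 1 fell (23 and 1 adjusted over the list alone), camera adjusted p = 5.0e-08, adjusted p = 0.054 with an estimated correlation, with Vim (1.04 ± 0.04). Of the macrophage markers 17 of 22 rose (17 adjusted over the list alone), camera adjusted p = 1.5e-04, adjusted p = 0.025 with an estimated correlation, with Lyz2 (0.82 ± 0.05). Of the epicardial markers 16 of 16 rose (16 adjusted over the list alone), camera adjusted p = 2.9e-06, adjusted p = 0.017 with an estimated correlation, with Krt8 (1.14 ± 0.05). Endothelial markers moved likewise (19 of 23 rose and 3 fell (19 and 3 adjusted over the list alone), camera adjusted p = 0.0015, adjusted p = 0.049 with an estimated correlation). Smooth muscle and pericyte markers went both ways (5 of 17 fell and 6 rose (5 and 6 adjusted over the list alone), camera adjusted p = 0.84, adjusted p = 0.85 with an estimated correlation), and so did those of Schwann cells and neurons (4 of 12 fell and 4 rose (4 and 4 adjusted over the list alone), camera adjusted p = 0.84, adjusted p = 0.85 with an estimated correlation). Of 37 gene lists, 25 passed limma camera with the preset correlation and 8 with an estimated correlation. Scaling by total counts alone shifted the median log2 fold change of all genes to 0.16 and made 58.9% of the calls higher, against 48.5% with TMM.

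The same treatment in the libraries labelled KO (KO_HR against KO_CT) gave much the same picture. Egr4 (8.36 ± 0.14), Fosb (7.20 ± 0.09) and Arc (6.58 ± 0.09) again led the rise, and Ckmt2 (-4.57 ± 0.08), Ryr2 (-4.32 ± 0.16) and Aqp4 (-4.35 ± 0.15), a water channel, the fall. All 26 immediate early genes rose (median log2 fold change 2.54) and all 30 cardiomyocyte markers fell (median -2.91, camera adjusted p = 1.3e-20, adjusted p = 0.079 with an estimated correlation). NRF2 genes rose (18 of 26 rose and 4 fell (18 and 4 adjusted over the list alone), camera adjusted p = 2.1e-05, adjusted p = 0.15 with an estimated correlation), with Hmox1 (3.41 ± 0.05). Ferroptosis defence rose (14 of 27 rose and 8 fell (14 and 8 adjusted over the list alone), camera adjusted p = 0.031, adjusted p = 0.17 with an estimated correlation), with Slc7a11 (2.34 ± 0.08). So did ATF4 targets (17 of 30 rose and 5 fell (17 and 6 adjusted over the list alone), camera adjusted p = 0.0015, adjusted p = 0.086 with an estimated correlation), with Atf4 (2.03 ± 0.05), and p53 targets (18 of 24 rose and 4 fell (18 and 4 adjusted over the list alone), camera adjusted p = 1.7e-06, adjusted p = 0.0045 with an estimated correlation), with Plk2 (2.95 ± 0.05). Fatty acid oxidation fell (23 of 24 fell (23 adjusted over the list alone), camera adjusted p = 2.0e-12, adjusted p = 0.049 with an estimated correlation), as in Acaa2 (-2.35 ± 0.05). In all 11828 genes were called by the same edgeR test, 5891 higher and 5937 lower. Limma camera called 26 of 37 lists with the preset correlation and 9 with an estimated correlation. With scaling by total counts 57.4% of the calls were higher, against 49.8%. With the pseudogene share as a covariate the count was 7200, 6876 of them among the 11828. Of the 11828 genes 95.3% kept their sign, with a median absolute log2 fold change of 0.66 (median SE 0.179) against 0.71 (median SE 0.085).

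Across the 17250 genes, which are not independent replicates, the 2 responses correlated at r = 0.88 (Spearman's correlation 0.91, leave-one-library-out SE 0.01). Of genes called in both, 10322 moved the same way and 14 the opposite way. Independent lists of these sizes would share 4043 and 4042. Without a filter on low counts r was 0.45.

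KO_CT against WT_CT asked how untreated cells differed by label. Matrix and fibroblast transcripts were higher in the libraries labelled KO, mostly by less than 2-fold. Mitochondrial, cholesterol and antioxidant transcripts were lower by the preset list test. With an estimated correlation the adjusted p was 0.079 for mitochondrially encoded mRNAs, 0.12 for oxidative phosphorylation, 0.11 for cholesterol synthesis and 0.11 for NRF2 genes in limma camera. Col1a1 (0.66 ± 0.04) and Col3a1 (0.62 ± 0.05), the main fibrillar collagens, and Postn (0.53 ± 0.04) were higher. The largest differences included Rarres2 (1.37 ± 0.11), which encodes chemerin, Myh7 (1.15 ± 0.14), the slow myosin heavy chain, and Wdfy1 (1.24 ± 0.07) on the higher side. On the lower side were the pacemaker channel Hcn4 (-1.03 ± 0.10), the atrial potassium channel Kcnj3 (-0.94 ± 0.09) and Slc7a11 (-0.79 ± 0.09). In all 2893 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1097 higher and 1796 lower, 78 and 32 of them by at least 2-fold.

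Fibroblast markers rose together in KO_CT (19 of 25 rose (21 adjusted over the list alone), camera adjusted p = 1.7e-22, adjusted p = 0.0044 with an estimated correlation). TGF-beta and myofibroblast genes did so too (20 of 27 rose (20 adjusted over the list alone), camera adjusted p = 4.7e-22, adjusted p = 0.0030 with an estimated correlation). Matrix metalloproteinases with their inhibitors were higher (15 of 20 rose and 1 fell (16 and 1 adjusted over the list alone), camera adjusted p = 6.3e-14, adjusted p = 2.5e-04 with an estimated correlation), such as Mmp2 (0.47 ± 0.05). Smooth muscle and pericyte markers were higher (8 of 17 rose and 1 fell (9 and 2 adjusted over the list alone), camera adjusted p = 8.3e-06, adjusted p = 0.0053 with an estimated correlation), with Notch3 (0.93 ± 0.07). So were endothelial markers (8 of 23 rose and 1 fell (9 and 1 adjusted over the list alone), camera adjusted p = 5.0e-05, adjusted p = 0.018 with an estimated correlation), with Fabp4 (0.93 ± 0.10). Ferroptosis defence genes were lower (13 of 27 fell (14 adjusted over the list alone), camera adjusted p = 1.8e-06, adjusted p = 0.018 with an estimated correlation), with Gclm (-0.31 ± 0.05) beside Slc7a11. NRF2 genes were lower by the preset correlation but not the estimated one (14 of 26 fell (17 and 1 adjusted over the list alone), camera adjusted p = 1.9e-07, adjusted p = 0.11 with an estimated correlation), and so were the next groups. Of the cholesterol synthesis genes 16 of 23 fell (18 adjusted over the list alone), camera adjusted p = 9.5e-11, adjusted p = 0.11 with an estimated correlation, with Cyp51 (-0.59 ± 0.07). Of the oxidative phosphorylation genes 24 of 33 fell (26 adjusted over the list alone), camera adjusted p = 1.8e-15, adjusted p = 0.12 with an estimated correlation, with Cox5a (-0.32 ± 0.04). Of the mitochondrially encoded mRNAs 7 of 13 fell (10 adjusted over the list alone), camera adjusted p = 2.1e-07, adjusted p = 0.079 with an estimated correlation. Of the cardiomyocyte markers 8 of 30 fell and 1 rose (16 and 1 adjusted over the list alone), camera adjusted p = 1.8e-06, adjusted p = 0.37 with an estimated correlation. Limma camera called 20 of 37 lists with the preset correlation and 6 with an estimated correlation. The pseudogene share was lower in KO_CT replicates 2 and 3 than in WT_CT. With it as a covariate 2524 genes were called, 1791 of them among the 2893. Of the 2893 genes called without it, 2892 kept their sign, with a median absolute log2 fold change of 0.29 against 0.27. With scaling by total counts 1658 calls were higher and 892 lower, where TMM gave more lower ones. The calls were 51.7% higher with no filter on low counts and 51.8% in a fit of the 6 libraries alone.

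KO_HR against WT_HR asked how the treated cells differed by label. Cardiomyocyte transcripts were lower in KO_HR, matrix and smooth muscle transcripts higher, and mitochondrially encoded mRNAs lower. Of 30 cardiomyocyte markers 23 fell (27 adjusted over the list alone), with a median log2 fold change of -0.48 (camera adjusted p = 5.5e-33, adjusted p = 0.056 with an estimated correlation). They were led by Ckmt2 (-1.01 ± 0.09), Csrp3 (-0.61 ± 0.06) and Smpx (-0.70 ± 0.09). Smooth muscle and pericyte markers were higher (12 of 17 rose (13 adjusted over the list alone), camera adjusted p = 3.0e-12, adjusted p = 6.4e-04 with an estimated correlation), with Notch3 (0.62 ± 0.07) and Myh11 (0.58 ± 0.06). TGF-beta and myofibroblast genes were higher too (16 of 27 rose (20 adjusted over the list alone), camera adjusted p = 5.8e-14, adjusted p = 0.012 with an estimated correlation), with Col3a1 (0.50 ± 0.05). The same held for fibroblast markers (13 of 25 rose (15 adjusted over the list alone), camera adjusted p = 3.0e-12, adjusted p = 0.027 with an estimated correlation). Mitochondrially encoded mRNAs were lower (10 of 13 fell and 1 rose (10 and 1 adjusted over the list alone), camera adjusted p = 7.8e-14, adjusted p = 0.021 with an estimated correlation), as in mt-Nd2 (-0.52 ± 0.05). In all 1538 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 696 higher and 842 lower, 49 and 37 by at least 2-fold. Of 37 gene lists, 24 passed limma camera with the preset correlation and 5 with an estimated correlation.

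Genes of the ferroptosis lists were lower in KO_HR by the preset test. Of the defence genes 11 of 27 fell (11 and 1 adjusted over the list alone), camera adjusted p = 2.4e-04, adjusted p = 0.056 with an estimated correlation, with Slc7a11 (-0.54 ± 0.07) and Gclc (-0.31 ± 0.05). Of the promoting genes 5 of 27 fell (5 adjusted over the list alone), camera adjusted p = 0.0010, adjusted p = 0.11 with an estimated correlation, with Tfrc (-0.34 ± 0.05), the transferrin receptor. Of the iron handling genes 5 of 28 fell (5 adjusted over the list alone), camera adjusted p = 0.025, adjusted p = 0.14 with an estimated correlation. The Fanconi list did not pass (camera adjusted p = 0.11, adjusted p = 0.29 with an estimated correlation). NRF2 genes were lower (13 of 26 fell (17 and 1 adjusted over the list alone), camera adjusted p = 7.5e-11, adjusted p = 0.056 with an estimated correlation), with Srxn1 (-0.50 ± 0.06). Muscarinic receptor Chrm2 (-0.88 ± 0.11), Kcnj3 (-0.80 ± 0.12) and Mylk3 (-0.75 ± 0.07), a cardiac myosin kinase, were among the largest falls. Ribosomal protein genes made up most of the largest rises, Rpl28 (1.2 ± 0.21), Rps6 (1.13 ± 0.19) and Rpl27 (1.09 ± 0.18). The list was higher as a whole (11 of 35 rose (16 adjusted over the list alone), camera adjusted p = 7.2e-11, adjusted p = 0.18 with an estimated correlation). With the pseudogene share as a covariate the list turned lower (median log2 fold change -0.10, camera adjusted p = 0.033). These genes share reads with pseudogenes and are uncertain: with pseudogene reads added to the parent genes, Rpl28 stood at 0.15, Rps6 at 0.04 and Rpl27 at -0.02. The pseudogene share was 41.7 to 45.4% in KO_HR and 66.1 to 67.8% in WT_HR. With that share as a covariate 114 genes were called. Of the genes called without it 76.2% kept their sign, with a median absolute log2 fold change of 0.22 (median SE 0.174) against 0.30 (median SE 0.069). Without WT_HR replicate 1, KO_HR replicate 2 or KO_HR replicate 3 the counts were 859, 792 and 867. A fit of the 6 libraries alone called 2400, and the higher share of calls was 59.2% with total counts and 32.9% in DESeq2, against 45.3%.

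The label differences of treated and untreated cells were then set against each other. Of genes called in both, 783 differed the same way and 10 the opposite way, where independent lists would share 132 and 126. Slc7a11, Col1a1, Col3a1, Kcnj3, Notch3 and Wdfy1 were among the former. Across genes r was 0.27 (Spearman's correlation 0.35, SE 0.09), and 0.048 with no filter on low counts.

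KO_HA against KO_HR asked what differed in treated cells labelled KO that had received the Atf3 virus. Cardiomyocyte transcripts were higher in KO_HA and ribosomal protein transcripts lower by the preset list test (camera adjusted p = 0.20 and 0.20 with an estimated correlation). Ckmt2 (2.05 ± 0.08), Pln (1.61 ± 0.12), the inhibitor of the sarcoplasmic calcium pump, Aqp4 (1.93 ± 0.17) and Chrm2 (1.51 ± 0.11) were among the 6 largest rises. The cardiomyocyte markers rose as a list (24 of 30 rose (24 adjusted over the list alone), camera adjusted p = 1.3e-19, adjusted p = 0.20 with an estimated correlation). Mitochondrially encoded mRNAs were higher (10 of 13 rose (11 adjusted over the list alone), camera adjusted p = 1.4e-09, adjusted p = 0.20 with an estimated correlation), with mt-Nd2 (0.71 ± 0.05). So was fatty acid oxidation (15 of 24 rose and 2 fell (17 and 2 adjusted over the list alone), camera adjusted p = 7.3e-08, adjusted p = 0.20 with an estimated correlation), with Acaa2 (0.61 ± 0.05). Of the ribosomal protein genes 33 of 35 fell (34 adjusted over the list alone), camera adjusted p = 3.7e-27, adjusted p = 0.20 with an estimated correlation, with Rpl8 (-0.63 ± 0.04) and Rplp0 (-0.55 ± 0.04). After pseudogene reads were added to the parents 35 of 35 fell, and their median log2 fold change was -0.44. In all 6255 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3043 higher and 3212 lower, 175 and 138 by at least 2-fold. This balance turned over in other settings, with 58.0% higher by DESeq2 size factors, 58.0% in DESeq2 and 58.4% with no filter on low counts, against 48.6%.

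Heat shock proteins were lower in KO_HA (12 of 20 fell and 2 rose (12 and 2 adjusted over the list alone), camera adjusted p = 1.8e-04, adjusted p = 0.20 with an estimated correlation), with Hspa1a (-0.72 ± 0.05). So were ATF4 targets (15 of 30 fell and 4 rose (16 and 4 adjusted over the list alone), camera adjusted p = 0.0044, adjusted p = 0.20 with an estimated correlation), with Nupr1 (-0.65 ± 0.06), though Slc7a11 (0.51 ± 0.07) rose. Interferon-stimulated genes were higher (15 of 34 rose and 2 fell (17 and 3 adjusted over the list alone), camera adjusted p = 0.0033, adjusted p = 0.60 with an estimated correlation), with Rsad2 (0.84 ± 0.09) and Iigp1 (0.76 ± 0.08). Cholesterol synthesis was higher too (14 of 23 rose and 2 fell (14 and 2 adjusted over the list alone), camera adjusted p = 0.0021, adjusted p = 0.53 with an estimated correlation), with Hmgcs1 (0.43 ± 0.05). Ferroptosis defence did not pass the list test and its members went both ways (10 of 27 fell and 7 rose (11 and 9 adjusted over the list alone), camera adjusted p = 0.83, adjusted p = 0.87 with an estimated correlation). By limma camera 11 of 37 lists passed with the preset correlation and 0 with an estimated correlation, which left 8 at an unadjusted p below 0.05, and 23 passed fry. The pseudogene share was 61.1 to 70.7% in KO_HA and 41.7 to 45.4% in KO_HR. With the share as a covariate 140 genes were called. Of those called without it 72.0% kept their sign, with a median absolute log2 fold change of 0.19 (median SE 0.183) against 0.34 (median SE 0.073).

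KO_HA against WT_HR set the virus group beside treated cells labelled wild type. Interferon-stimulated and mitotic genes were higher in KO_HA, and heat shock, NRF2 and ribosomal protein genes lower, by the preset list test. With an estimated correlation these calls were lost (camera adjusted p = 0.22, 0.17, 0.16, 0.19 and 0.17 in that order). Of the interferon genes 20 of 34 rose (22 adjusted over the list alone), camera adjusted p = 8.2e-09, adjusted p = 0.22 with an estimated correlation, with Gbp2 (0.60 ± 0.08). Of the mitotic genes 17 of 30 rose and 2 fell (20 and 2 adjusted over the list alone), camera adjusted p = 1.5e-06, adjusted p = 0.17 with an estimated correlation, with Top2a (0.47 ± 0.05) and Mki67 (0.55 ± 0.07). Fancd2 (0.67 ± 0.16) rose, and the Fanconi list with it (6 of 28 rose (6 adjusted over the list alone), camera adjusted p = 0.0057, adjusted p = 0.17 with an estimated correlation), as in Brca2 (0.78 ± 0.15). Heat shock proteins were lower (14 of 20 fell and 1 rose (14 and 1 adjusted over the list alone), camera adjusted p = 3.1e-08, adjusted p = 0.16 with an estimated correlation), with Bag3 (-0.45 ± 0.04). So were NRF2 genes (17 of 26 fell and 1 rose (18 and 1 adjusted over the list alone), camera adjusted p = 2.3e-07, adjusted p = 0.19 with an estimated correlation), with Osgin1 (-0.65 ± 0.07). Ribosomal protein genes fell too (28 of 35 fell (32 adjusted over the list alone), camera adjusted p = 1.3e-21, adjusted p = 0.17 with an estimated correlation), with Rplp0 (-0.52 ± 0.04). Cardiomyocyte markers were higher by the preset correlation but not the estimated one (12 of 30 rose and 3 fell (14 and 4 adjusted over the list alone), camera adjusted p = 1.6e-04, adjusted p = 0.51 with an estimated correlation). Ckmt2 (1.04 ± 0.08) was higher, and Myl4 (-0.65 ± 0.08), the atrial light chain, lower. The largest differences were Aqp4 (1.43 ± 0.16), Gpd1 (1.34 ± 0.13) and Wdfy1 (1.22 ± 0.07) above. Below were Erdr1 (-1.17 ± 0.17), Plac9a (-1.06 ± 0.13) and Col2a1 (-1.01 ± 0.06). In all 5073 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2391 higher and 2682 lower. Here too the balance turned over, to 53.9% higher by DESeq2 size factors, 52.8% in DESeq2, 57.6% with no filter and 51.4% by total counts, against 47.1%. By limma camera 21 of 37 lists passed with the preset correlation and 0 with an estimated correlation, which left 8 at an unadjusted p below 0.05, and 27 passed fry.

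Many genes that differed between KO_HR and WT_HR went the opposite way between KO_HA and KO_HR. Of 1538 genes, 968 (62.9%) did so and 68 moved further in the same direction, where independent lists would share 278 and 280. The genes that moved most on both sides included Zan (2.3 ± 0.29 in KO_HR against WT_HR, then -2.12 ± 0.28 with the virus, both log2 fold changes) and Lrrc14b (-1.80 ± 0.32 and 2.14 ± 0.30). Others were the long noncoding RNA Ftx (1.59 ± 0.19 and -1.69 ± 0.19), Lypd8l (-1.10 ± 0.32 and 3.11 ± 0.24) and Rps6 (1.13 ± 0.19 and -1.53 ± 0.19). Rps6 shares reads with pseudogenes. With these reads added it stood at 0.04, no longer called, and at -0.31, still called. Both comparisons use the KO_HR libraries, which alone gives opposite signs. Across genes r was -0.61, against -0.48 on average in 20 simulations of unchanged groups. The covariance was -0.14 against -0.032, a difference of -0.108. With KO_CT against WT_CT as the label difference, which shares no library with the virus comparison, 890 genes went the opposite way and 571 the same way (independent lists, 521 and 528), at r = -0.075. With the pseudogene share as a covariate 26 genes went the opposite way. Without WT_HR replicate 1, KO_HR replicate 2 or KO_HR replicate 3 the number was 576, 511 and 538.

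The interaction asked whether the response to hypoxia and reoxygenation differed by label. It did for 165 genes (91 with a higher and 74 with a lower response in the libraries labelled KO, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Atf3 itself was just short of the threshold (log2 difference 0.36 ± 0.09, adjusted p = 0.052 in the same edgeR test with Benjamini-Hochberg adjustment). Dlc1 (0.60 ± 0.06) and the endothelin receptor Ednra (0.71 ± 0.14) had a higher response in the libraries labelled KO, and Myh7 (-1.29 ± 0.23) and the ventricular transcription factor Irx4 (-1.01 ± 0.20) a lower one. By list, cardiomyocyte markers had lower responses (3 of 30 fell (6 adjusted over the list alone), camera adjusted p = 3.8e-13, adjusted p = 0.29 with an estimated correlation). Cardiac stress genes did as well (2 of 14 fell (5 adjusted over the list alone), camera adjusted p = 3.9e-05, adjusted p = 0.22 with an estimated correlation). ATF4 targets had higher ones (3 of 30 rose (6 adjusted over the list alone), camera adjusted p = 2.1e-04, adjusted p = 0.13 with an estimated correlation), with Atf4 (0.29 ± 0.07). NF-kB feedback genes followed them (2 of 18 rose (4 adjusted over the list alone), camera adjusted p = 3.1e-04, adjusted p = 0.13 with an estimated correlation), with Nfkbia (0.35 ± 0.07). Metalloproteinases and their inhibitors had lower responses by both correlations (1 of 20 fell (2 adjusted over the list alone), camera adjusted p = 3.7e-05, adjusted p = 0.023 with an estimated correlation). Fibroblast markers (3 of 25 fell (8 adjusted over the list alone), camera adjusted p = 8.5e-08, adjusted p = 0.13 with an estimated correlation) had lower ones by the preset correlation. TGF-beta and myofibroblast genes moved with them (3 of 27 fell (8 and 1 adjusted over the list alone), camera adjusted p = 4.9e-06, adjusted p = 0.13 with an estimated correlation). Of 37 gene lists, 16 passed limma camera with the preset correlation and 1 with an estimated correlation. With the pseudogene share as a covariate 25 genes were called, 4 of them among the 165. Among those called without it 99.4% kept their sign, with a median absolute log2 fold change of 0.32 (median SE 0.125) against 0.42 (median SE 0.089). The share of higher responses was 26.4% with total counts, 40.9% with DESeq2 size factors and 28.1% with no filter on low counts, against 55.2%. The count was 424 with no filter, 272 in DESeq2, 291 with the replicate number as a block, 80 without WT_CT replicate 2, 64 without WT_CT replicate 3, 86 without KO_CT replicate 2, 352 without KO_CT replicate 3, 89 without WT_HR replicate 1, 88 without WT_HR replicate 2, 62 without KO_HR replicate 2 and 77 without KO_HR replicate 3.

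**Figure D3:**
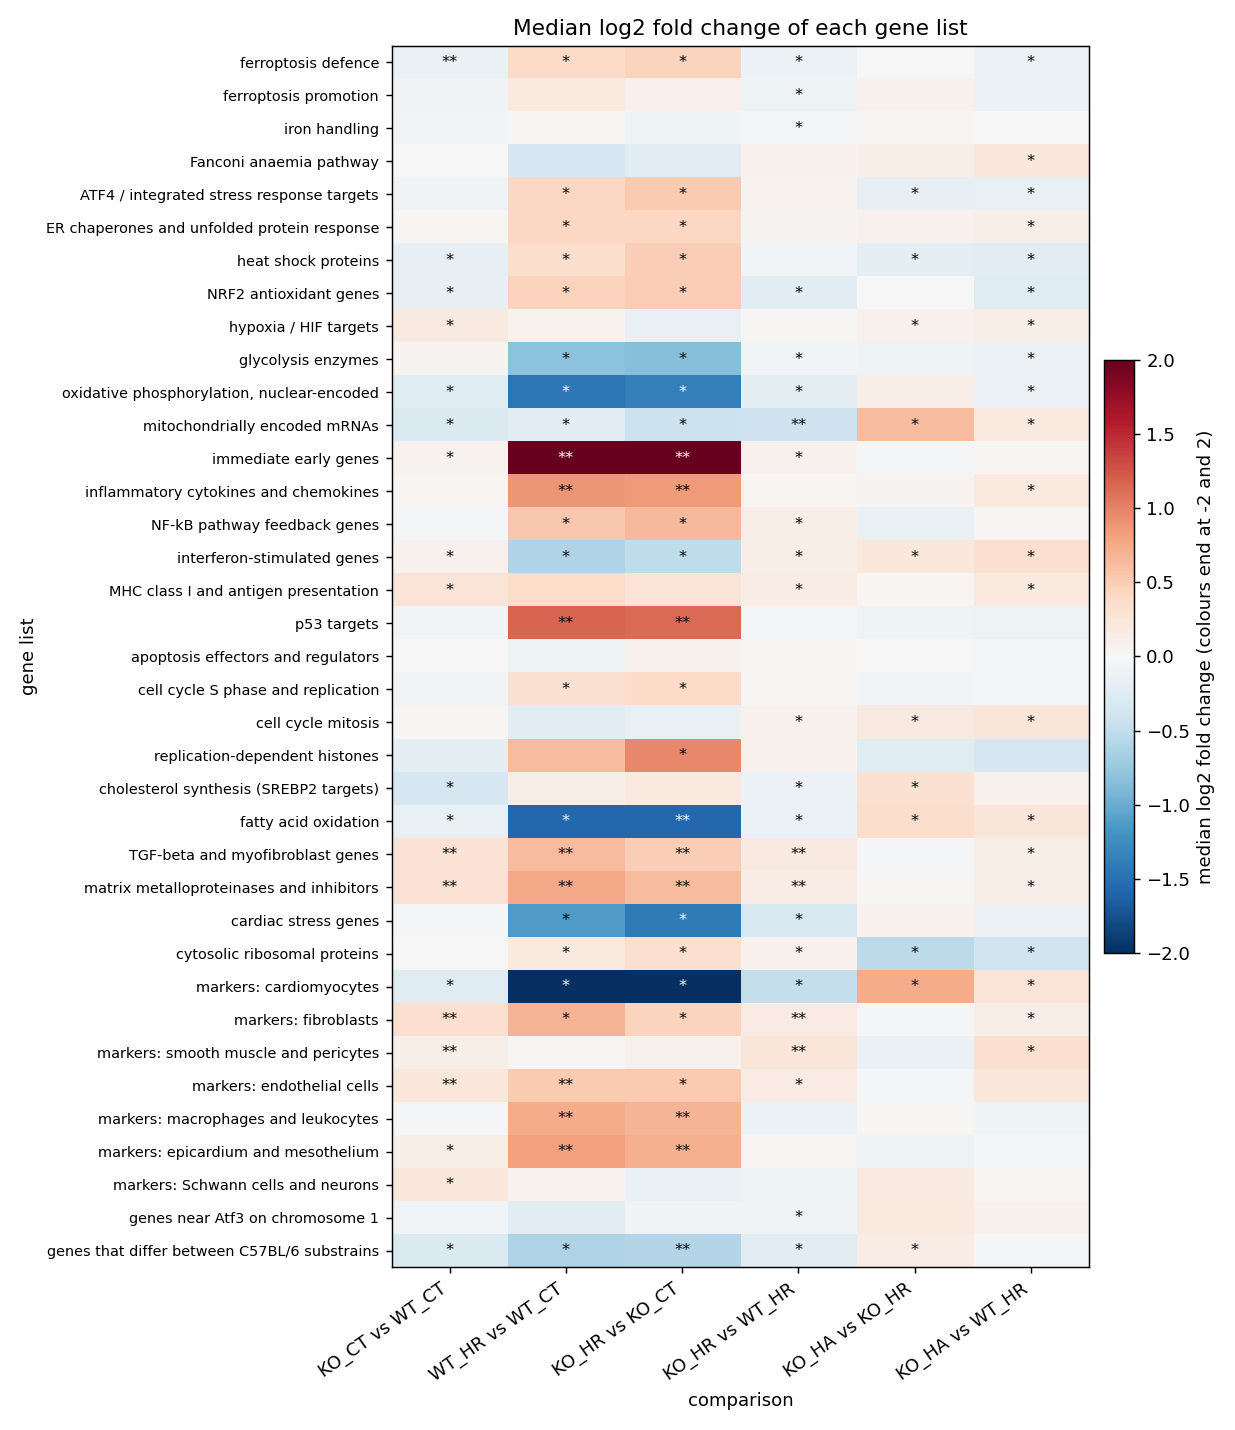
Median log2 fold change (colour, limited to 2 either way) of the 37 gene lists in 6 comparisons. One star marks a list past limma camera with the preset correlation only, and a pair of stars a list also past it with an estimated correlation. Cardiomyocyte markers stand at -2.64 in WT_HR against WT_CT, -0.48 in KO_HR against WT_HR and 0.74 in KO_HA against KO_HR.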

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

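Of the tests in this part, only the fit with the pseudogene share as a covariate was chosen only after the result was seen. A difference between groups, tested by the interaction of label and treatment, is what singles out the results below. For 165 genes the response to hypoxia and reoxygenation differed between the libraries labelled KO and those labelled wild type, by the interaction term of edgeR's quasi-likelihood test. 10 of 100 splits of the 12 libraries by label, drawn with the real one among them, called at least as many. The real one called 165 and the highest other 3854. The other splits that called as many kept the labels of 3 untreated and 0 treated KO libraries (the highest), 3 and 1, 2 and 0, or 0 and 2. Each carries the label difference itself into the interaction, a structure of the samples, so these splits neither exclude chance nor speak for it. The count was 80 without WT_CT replicate 2, 64 without WT_CT replicate 3, 86 without KO_CT replicate 2, 352 without KO_CT replicate 3, 89 without WT_HR replicate 1, 88 without WT_HR replicate 2, 62 without KO_HR replicate 2 and 77 without KO_HR replicate 3, and with the pseudogene share as a covariate 25. Only 4 of these 25 were among the 165. With the covariate 99.4% of the 165 kept their sign, with a median absolute log2 fold change of 0.32 (median SE 0.125) against 0.42 (median SE 0.089).

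The genes that the naming rule gives for the difference in response follow, each with the log2 fold change in libraries labelled KO minus that in libraries labelled wild type. Psd differed by 1.03 ± 0.20 (it rose by 1.99 with treatment in the libraries labelled KO and by 0.95 in the others). Ednra differed by 0.71 ± 0.14, with -1.10 and -1.80, and Adcy1 by 0.57 ± 0.14, with -0.60 and -1.17. Dlc1 differed by 0.60 ± 0.06 and moved in opposite directions, 0.19 and -0.42. Myh7 differed by -1.29 ± 0.23, with -3.52 and -2.23, and Gipr by -1.27 ± 0.22, with -3.19 and -1.92. In untreated cells Myh7 and Gipr were higher in the libraries labelled KO, by 1.15 ± 0.14 and 0.88 ± 0.12. Asb11 differed by -1.01 ± 0.19, with -3.84 and -2.82, and Irx4 by -1.01 ± 0.20, with -4.10 and -3.09. Among the gene lists, metalloproteinases and their inhibitors differed with both the preset and the estimated correlation, with a median difference of -0.12. Of their members 1 of 20 fell (2 adjusted over the list alone). Fibroblast markers (median -0.16, 3 of 25 fell (8 adjusted over the list alone), limma camera adjusted p = 8.5e-08, adjusted p = 0.13 with an estimated correlation) moved the same way by the preset correlation. TGF-beta and myofibroblast genes did too (median -0.09, 3 of 27 fell (8 and 1 adjusted over the list alone), limma camera adjusted p = 4.9e-06, adjusted p = 0.13 with an estimated correlation).

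KO_CT replicate 1 stood apart from its group, with 2.93 on the second principal component against -15.4 and -15.7, and with the highest pseudogene share of the 3 (67.1% against 59.6% and 57.1%). Without it 2467 genes were called for KO_CT against WT_CT, 11365 for KO_HR against KO_CT and 128 for the interaction.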

How the results depend on the processing

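The pseudogene reads added to parents, the covariate and the libraries with a share over 65% were chosen only after the result was seen. Over the alternatives chosen in advance, named genes kept their call, or lack of it, in 11397 of their refits, lost it in 486 and gained it in 6. For lists these numbers were 2754, 185 and 132, with the estimated correlation and fry included. Lists were not tallied with total counts, a mean of at least 1 CPM, the 6 libraries alone or DESeq2's own test. No direction reversed where either fit made a call. Where neither did, directions were not compared. The cause was not tested unless it is given.

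The covariate is nearly confounded with KO_HR, so calls ended through a larger error as well as smaller changes. For genes called in KO_HR against WT_HR, the median SE went from 0.069 to 0.174, the median absolute log2 fold change from 0.30 to 0.22, and 76.2% kept their sign. For KO_HA against KO_HR, the SE went from 0.073 to 0.183, the size from 0.34 to 0.19, and 72.0% kept their sign. For KO_HR against KO_CT 95.3% kept their sign, with a median absolute log2 fold change of 0.66 (median SE 0.179) against 0.71 (median SE 0.085). For the interaction 99.4% kept their sign, with a median absolute log2 fold change of 0.32 (median SE 0.125) against 0.42 (median SE 0.089). The counts became 7200 (KO_HR against KO_CT), 114 (KO_HR against WT_HR), 140 (KO_HA against KO_HR), 25 (interaction) and 26 (opposite with the virus). In the comparisons named, 6876, 34, 121 and 4 of these, in that order, were also called without the covariate. Counts stayed of similar size in the comparisons without KO_HR, at 2524 (KO_CT against WT_CT), 11756 (WT_HR against WT_CT) and 5458 (KO_HA against WT_HR). Of these, 1791, 11498 and 5059 were also called without the covariate, so the KO_CT calls turned over in part. Of the genes called without it, 2892 of 2893 kept their sign for KO_CT against WT_CT, and all did in the other comparisons. The response correlation became 0.82 and the label correlation 0.62. Both label differences then subtract the same estimated slope, whose error raises the latter, so it shows no agreement. With the covariate these log2 fold changes changed sign and none of the genes was called: in KO_HR against WT_HR, Rpl28 -0.49, Rps6 -0.27, Rpl27 -0.32, Rps23 -0.28, Rpl13 -0.091, Slc38a1 0.0032, Vdac2 0.021, Fth1 0.12, Shmt2 -0.015, Serpinh1 -0.0090, Pdk1 0.029, Ndufb5 0.040, Egr2 -0.0068, Ier5 -0.062, Nfkb1 -0.061, Bst2 -0.018, Psmb8 -0.087, H2-T23 -0.082, Trp53inp1 0.10, Ccng1 0.15, Krt7 -0.14, Nenf -0.081, Prox1 0.091, Slamf1 -0.35. In KO_HA against KO_HR they were Fancd2 -0.043, Rpl28 0.072, Tfrc -0.0042, Sec61b 0.097, Maff 0.050, Jund 0.21, Ier5 0.081, Nos2 -0.088, Psmb8 0.089, B2m -0.15, Ccng1 -0.037, Bak1 0.024, Pold1 0.025, Anln -0.021, Prox1 -0.054, Slamf1 0.27. Lists whose direction in limma camera changed had these medians: in KO_HR against WT_HR, NF-kB pathway feedback genes -0.073, MHC class I and antigen presentation -0.087, cytosolic ribosomal proteins -0.10. Of these, the ribosomal list passed limma camera in the new direction (adjusted p = 0.033). They were hypoxia / HIF targets -0.12 in KO_HA against KO_HR, cytosolic ribosomal proteins -0.036 in the interaction, and cytosolic ribosomal proteins -0.079 in KO_CT against WT_CT, from an uncalled -0.0058 (camera adjusted p = 0.021), where it was -0.10 with only libraries over 65% (camera adjusted p = 1.1e-05). With pseudogene reads added, Rpl27 stood at -0.024 in KO_HR against WT_HR, and the response correlation at 0.91. Libraries over 65% alone gave 2579 genes for KO_CT against WT_CT and 4933 for KO_HA against WT_HR, where the lone KO_CT library is assumed to vary like the other groups.

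Among the other settings, the 6 libraries alone gave 2400 genes for KO_HR against WT_HR. The interaction gave 424 with no filter and 272 in DESeq2. With no filter, which adds low genes, the response correlation was 0.45 and the label correlation 0.048, and with a mean of at least 1 CPM 0.92 and 0.36. The share of higher calls also moved for KO_CT against WT_CT, from 37.9% to 51.7% with no filter and 51.8% with 6 libraries. Total counts moved the median of all genes to 0.16 in WT_HR against WT_CT and to 0.14 in KO_HR against KO_CT, and the calls for KO_CT against WT_CT to 1658 higher and 892 lower. The share of higher calls became 58.9% for WT_HR against WT_CT, 59.2% for KO_HR against WT_HR and 26.4% for the interaction. Leaving out 1 library gave 1938 to 2762 genes for KO_CT against WT_CT, 11247 to 11283 for WT_HR against WT_CT, 11191 to 11533 for KO_HR against KO_CT, 792 to 1502 for KO_HR against WT_HR, 5152 to 5891 for KO_HA against KO_HR, 4116 to 4537 for KO_HA against WT_HR and 62 to 352 for the interaction, with 511 to 1021 genes opposite with the virus, a response correlation of 0.853 to 0.866 and a label correlation of 0.176 to 0.288. Counts that moved by over 1.5 times were, for KO_HR against WT_HR, 859 without WT_HR replicate 1, 792 without KO_HR replicate 2 and 867 without KO_HR replicate 3, for the genes opposite with the virus, 576 without WT_HR replicate 1, 511 without KO_HR replicate 2 and 538 without KO_HR replicate 3, and for the interaction, 80 without WT_CT replicate 2, 64 without WT_CT replicate 3, 86 without KO_CT replicate 2, 352 without KO_CT replicate 3, 89 without WT_HR replicate 1, 88 without WT_HR replicate 2, 62 without KO_HR replicate 2 and 77 without KO_HR replicate 3. At 16714900 counts or more per library, depth limits low genes such as Fancd2.

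Whether replicate numbers pair the samples is not settled. Over 30 same-number pairs the correlation of deviations ran from -0.12 to 0.31, with 10 over 0.1. Its median was 0.036, against -0.029 for other pairs. As a hint from the data, 11 of 15 libraries correlated best with their own number. With the replicate number as a block, the interaction called 291 genes (165 without it), KO_HR against WT_HR 1777 (1538) and KO_CT against WT_CT 3130 (2893).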

Other observations

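The tests of ribosomal and mitochondrial reads, of the cardiomyocyte share, of a deleted allele and of the virus were chosen only after the result was seen, and so were Col6a3, Sparcl1 and Fam71a as genes to name. Further gene groups moved in part with hypoxia and reoxygenation. Of the targets of the hypoxia factor HIF in WT_HR against WT_CT, 11 rose and 12 fell (camera adjusted p = 0.97). Pdk1 (-1.41 ± 0.06) and Ldha (-0.84 ± 0.04) were among those that fell. Of the interferon-stimulated genes, 21 of 34 fell and 5 rose (21 and 5 adjusted over the list alone), limma camera adjusted p = 0.0015, adjusted p = 0.39 with an estimated correlation. Among them Iigp1 (-2.42 ± 0.07) and Stat2 (-1.60 ± 0.07) fell, while Cxcl10 (1.83 ± 0.06), a chemokine on both the interferon and the inflammatory list, rose. Of the S phase genes, 18 of 30 rose and 6 fell (18 and 6 adjusted over the list alone), limma camera adjusted p = 0.010, adjusted p = 0.22 with an estimated correlation. Among them Pcna (0.72 ± 0.05) rose, and Cenpf (-0.98 ± 0.09) of the mitotic list fell.

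Some genes were called the same way in untreated cells, in treated cells and in the virus group, each against libraries labelled wild type. The last pair of comparisons shares the WT_HR libraries, which alone gives agreement, so the genes are given as values only. Wdfy1 (log2 fold change 1.24 ± 0.07, 1.07 ± 0.07 and 1.22 ± 0.07), in that order, was at 50.1 to 59.2 CPM in the 9 libraries labelled KO and 21.9 to 27.6 in the others, and is on the list of genes that differ between C57BL/6 substrains. In KO_CT against WT_CT 4 of 7 members of that list fell and 1, Wdfy1, rose (5 and 1 adjusted over the list alone), limma camera adjusted p = 0.035, adjusted p = 0.11 with an estimated correlation. Of all genes 16.8% were called there. The list sets no direction for its members, so their mixed signs speak neither for nor against a substrain difference, which was not tested. Col6a3 (log2 fold change 0.89 ± 0.06, 0.65 ± 0.05 and 0.74 ± 0.05), Sparcl1 (log2 fold change 0.78 ± 0.08, 0.90 ± 0.07 and 1.17 ± 0.07) and Notch3 (log2 fold change 0.93 ± 0.07, 0.62 ± 0.07 and 0.49 ± 0.07) were further such genes.

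Of the 1538 genes called between KO_HR and WT_HR, 968 also stood on the same side of KO_HA in KO_HR, which had the lowest pseudogene share. A lower share of cardiomyocytes as the only difference would move the other cell types alike, whereas smooth muscle and macrophage markers moved apart by 0.344 log2 units (SD 0.0524, no overlap). These lists had the highest and lowest median of the other cell types (0.24 and -0.12). They were chosen after the result was seen, so part of their separation comes from that choice and the test does not decide. The range of those medians, 0.358, is the same pair and adds nothing. In untreated cells smooth muscle markers already stood higher in KO_CT than in WT_CT (median log2 fold change 0.11), and macrophage markers did not (-0.018). A lower share beside such a standing label difference therefore stays open. Nuclear copies are argued against as the only cause of the mitochondrial fall, since with their reads added 11 of 13 members were called lower. The median stayed at -0.41, but it could hardly move, as only some members had a linked copy. The size of the fall did depend on the copies in some genes. With their reads added mt-Co3 went from -2.36 to -0.38 and mt-Co2 from -0.96 to -0.29, both still called. Reads shared with pseudogenes may account for the ribosomal rise in part: the 5 called members with at least 10% of family counts on pseudogenes went from a median of 0.98 to 0.098 with these reads added (2 still called), but an earlier form of the test on the whole list failed, from 0.09 to 0.07, and Rps29, with few such reads, stayed at 0.81. A difference between libraries that also moves pseudogene reads may contribute too, since over the 1538 genes the change toward a lower share within KO_CT and within KO_HA, which share no library with the comparison, correlated with it at 0.517 and 0.466, against 0.027 in WT_CT, where the share hardly varied. Each slope rests mostly on 1 of 3 libraries, KO_CT replicate 1, the deepest and apart from its group, and KO_HA replicate 3, while KO_HA replicates 1 and 2, alike in share (70.6% and 70.7%), differed from the rest of their group with correlations of -0.079 and -0.398, so whether the difference is technical or a state of the cells stays open.

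The 6255 genes of KO_HA against KO_HR cannot be told apart from an effect of the virus without Atf3, as no control virus was analysed.

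Atf3 was present in the libraries labelled KO, where KO_HR held 79.6% of the WT_HR level. A mix-up of single treated libraries is argued against by a score of the genes that differed at least 2-fold between KO_CT and WT_CT: the lowest of the 6 treated libraries labelled KO (0.27) lay 0.328 above the highest WT_HR library (-0.058). Labels exchanged in every group would pass that score, and Atf3 would then still be present in both genotypes. A transcript still made from a deleted allele cannot be told apart from an intact gene by counts per gene. DNA carried over around Atf3 from another strain also stays open, as 13 of 191 genes within 20 Mb differed the same way in both conditions (6.81%, against 4.55% of all placed genes), a higher share than in 92.6% of windows.

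Some genes that were near silent before treatment rose at least 8-fold with treatment under both labels, and a hypothesis is that transcription ran on into them from an upstream gene. Of 90 such genes, 46 (51.1%) had an expressed gene ending within 50 kb upstream on the same strand, against 313 of 966 other near-silent genes (32.4%, Fisher's exact, 2-sided, p = 6.6e-04). On the opposite strand the shares were 23.3% and 21.4% (Fisher's exact p = 0.69). The excess is below the 2-fold set in advance and the idea may hold for some of these genes. Fam71a, which follows Atf3, went from 0 to 1.45 CPM, whereas Kprp, from 0.188 to 22.6 CPM, has no such neighbour.

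Each of the 6 comparisons of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, and in each 1 split, the real one, called as many genes. Every other split mixes libraries of the compared groups, so a difference between the groups enters the spread and few calls follow. The gap between the counts below therefore does not exclude chance. The real count and the highest of the other splits were 2893 and 5 for KO_CT against WT_CT, 11791 and 0 for WT_HR against WT_CT, 11828 and 0 for KO_HR against KO_CT, 1538 and 2 for KO_HR against WT_HR, 6255 and 0 for KO_HA against KO_HR, 5073 and 0 for KO_HA against WT_HR.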
